A study of Mus musculus with 2 samples.

How the data were processed

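Brachiocephalic arteries were digested with Liberase and elastase for 60 min at 37 °C, pooled within each group, stained with a viability dye and sorted for live cells, per the labels' protocols. Libraries were made with a 10x Genomics Chromium 3′ kit, in which each droplet's bead carries 1 cell barcode and reads come from the 3′ end of transcripts. The submitters' processing notes name Cell Ranger 9.0.1, R 4.4.3, Seurat 5.3.0 and the mouse build GRCm39. They give no role or order for these tools, and further settings are not given in the sources used here. The deposited lists belong to the filtered feature-barcode output, as their names state. The rule that separated cells from empty droplets, and any removal of doublets, are not given in the sources used here, so the number of barcodes is not a number of verified single cells.

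The lists hold text and no measurement values: the authors' barcode lists give 1 cell barcode of 16 bases per line with the droplet-run suffix, which was a single value in both libraries, and the authors' feature lists give an identifier, a name and a feature type per gene. Count values per gene and cell were not analysed here. Analyses planned for such values (UMIs and genes per cell, cell type composition, expression by cell type and reporter transcripts) were therefore not run. Total counts per library are likewise not reported, and the precision of each number below is that of counting barcodes.

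Samples were grouped by their treatment label, with 1 pooled library per group, Control (4 mice) and Irradiated (3 mice). Barcodes were counted per library with exact Poisson 95% intervals, and the ratio of the libraries was given an exact binomial 95% interval. Barcodes were compared between libraries on the 16-base sequence. The sequences fell into a first segment of 7 bases, with 960 forms seen, and a second segment of 9 bases, with 3838 forms seen, whose combinations make a pool of 3684480. The number of shared barcodes expected by chance was computed from the segment frequencies in each library. Pairs of barcodes that differ at 1 base were counted within and between libraries, with the number expected if first and second segments combined at random. These calculations were tested on 5 simulated pairs of libraries of the real sizes. With 100 planted shared barcodes, the mean excess found was 93.0. The simulated segments were drawn uniformly, so this did not test the use of uneven segment frequencies. For the real libraries, uniform draws gave 238.3 expected shared barcodes, and the observed frequencies gave 240.0. For pairs differing at 1 base, 25 planted were found as 25, with 0 found where none was planted. The simulated draws left out the rarer member of every pair of second segments that differ at 1 base. The 0 was therefore fixed in advance, and the 25 checks only the counting of pairs, not the number expected by chance.

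Feature lists were compared entry by entry between libraries. The lists of cell type markers and pathway genes, the settings and their alternatives were fixed before the data were examined. The genes named are, by the rule fixed then, list members that are not listed (there were 0), features that are not mouse Ensembl genes, the genes that the genotype names (Myh11, Cdh5 and Apoe) and Ptprc. The list members given as examples were picked freely to illustrate each list and have no values. Members were matched by exact gene name. Some list members are not reported here by name. Gene types and overlapping neighbours were taken from GENCODE M21, an annotation of the older build GRCm38, by Ensembl identifier without version. Overlaps were found from its exon positions on GRCm38. No coordinates are printed, since the builds differ. Of the identifiers matched, 47203 (91.7%) also had the same gene name. The alternatives were counting distinct sequences, leaving out barcodes within 1 mismatch of another, matching with the suffix or with up to 1 mismatch, counting distinct gene names, and ignoring letter case. Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1 were used.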

Results

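Single-cell RNA-seq libraries were made from brachiocephalic arteries of female Apoe-deficient mice, a model in which a Western diet produces atherosclerotic lesions. The mice carried Myh11-DreERT2, Cdh5-CreERT2 and the Rosa-IR1 reporter allele, so that the smooth muscle and endothelial lineages could be traced in the same animal. Myh11 encodes smooth muscle myosin heavy chain, and Cdh5 encodes VE-cadherin, the adhesion molecule of endothelial junctions. The comparison set by the labels is between control mice and mice given lethal irradiation followed by bone marrow transplantation, and the question named by the series is how irradiation changes the cellular composition of lesions. The irradiated mice received 2 doses of 600 cGy, 3 hours apart, and marrow from Apoe-deficient donors carrying the CD45.1 variant of the leukocyte surface protein CD45. Control mice received saline and no irradiation. Both groups drank antibiotic water for 6 weeks from 9 weeks of age and were then fed the Western diet, for 18 weeks according to the label of each library and for 18 to 20 weeks according to the series.

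There was 1 library per group. The Control library pooled the arteries of 4 mice and the Irradiated library those of 3 mice. No difference between the groups therefore has a replicate check, and no test of the conditions was made. What was examined here was the list of cell barcodes and the list of features (genes and reporter sequences) of each library. Transcript counts per cell were not analysed here, so no statement is made about expression, cell type composition, reporter-positive cells or sequencing depth per cell in either group.

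The Irradiated library held more cell barcodes than the Control library. The Control library listed 27085 barcodes (exact Poisson 95% interval 26763 to 27410) and the Irradiated library 32420 (32068 to 32775). The ratio of Irradiated to Control was 1.20 (exact 95% interval 1.18 to 1.22), which is 19.7% more barcodes from fewer animals. Divided by the number of mice pooled, this came to 6771 barcodes in the Control library and 10807 in the Irradiated library. The arteries were pooled before the sort, so these values are not measured yields per animal. The intervals cover counting error only. Live cells were sorted and counted before library preparation, and the number loaded is not given in the sources used here, so the sort and the load can set this ratio.

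Few barcode sequences were common to both libraries. Of all sequences, 243 occurred in both libraries (exact Poisson 95% interval 213 to 276), which was 0.897% of the Control barcodes and 0.750% of the Irradiated barcodes. If each library had drawn its barcodes independently, at the frequencies of the barcode segments seen in it, 240.0 shared sequences would be expected, a value inside that interval. The overlap alone implied a pool of 3613563 possible barcodes (95% interval 3186685 to 4114690, Lincoln-Petersen estimate).

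Both lineage reporters were listed as features in both libraries, and whether reads were assigned to them was not examined. The feature lists of the libraries were identical and held 78241 entries, of which 78239 were mouse Ensembl genes and 2 were added sequences, tdTomato (a red fluorescent protein) and ZsGreen (a green fluorescent protein). The labels used here do not state which reporter follows which recombinase. No feature was named for the Dre or the Cre recombinase. The endogenous genes whose regulatory sequences drive the recombinases were listed, Myh11 as ENSMUSG00000018830.11 and Cdh5 as ENSMUSG00000031871.10. Apoe, which encodes apolipoprotein E and is disrupted in these mice, was listed as ENSMUSG00000002985.17. Ptprc, which encodes CD45, was listed as ENSMUSG00000026395.17. It was 1 feature, so a gene-level count of Ptprc would not separate the donor CD45.1 allele from other alleles.

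The features included every marker of the cell types for which lists had been fixed. This says which genes could be counted, and nothing about which cells were in the libraries. The 22 fixed lists of cell type markers held 120 distinct genes, and all 120 were listed under the exact gene name. They included all 8 contractile smooth muscle genes (among them Acta2, Tagln and Cnn1), all 8 genes of modulated smooth muscle (such as Lgals3 and Spp1) and all 6 of chondrocyte-like cells (such as Sox9 and Acan). All 8 endothelial genes (such as Pecam1 and Vwf), 5 lymphatic endothelial genes (such as Prox1) and 8 fibroblast genes (such as Pdgfra and Dcn) were also listed. So were the leukocyte lists, with 8 macrophage genes (such as Csf1r and Trem2), 5 monocyte genes (such as Ccr2), 6 neutrophil genes (such as S100a8), 7 T cell genes (such as Cd3e) and 5 B cell genes (such as Cd79a). The lists for dendritic, mast, natural killer, group 2 innate lymphoid, plasma, Schwann or neuronal, adipocyte, erythroid, cardiac muscle, mesothelial and cycling cells were complete as well, with 3 to 6 genes each.

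The 7 fixed pathway lists were likewise complete. They held 79 distinct genes, 13 of which formed the DNA damage and p53 list (such as the cell cycle inhibitor Cdkn1a and the p53 regulator Mdm2). The interferon response list had 12 genes (such as Ifit1 and Isg15), the list of inflammatory cytokines and adhesion 10 (such as Il1b and Vcam1), and the extracellular matrix list 14 (such as Col1a1 and Fn1). Lipid handling had 12 (such as the cholesterol exporter Abca1), endothelial to mesenchymal transition 11 (such as Snai1), and senescence secretory genes 8 (such as Igfbp7). Over all 29 lists, 190 of 190 distinct genes were listed, each on a single Ensembl identifier. A listed gene is one that could be counted, not one that was expressed.

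The feature list was broad. Of the 78239 Ensembl genes, 21830 (27.9%) had no name other than their identifier and 28315 (36.2%) had a Gm-numbered name, the form used for predicted mouse genes. There were 37 mitochondrially encoded genes. Of all Ensembl genes, 51498 (65.8%) matched an identifier in GENCODE M21. Among these, 21735 (42.2%) were protein-coding, 13425 (26.1%) were pseudogenes and 12743 (24.7%) were long non-coding RNAs or transcribed loci of undecided type. Gene names were not unique, since 312 names stood on more than 1 identifier, covering 629 features.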

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

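All 8 alternatives run, over 5 results, stayed within 1.5 times the reported value. That band is wider than the ratio of 1.20 between the libraries, so staying within it says nothing about that ratio. Counting distinct sequences left 27085 and 32420 barcodes. With a single suffix value, those counts could change only if a line was repeated. Leaving out barcodes that lie within 1 mismatch of another barcode of the same library left 27032 in the Control library and 32390 in the Irradiated library. Matching with up to 1 mismatch left 243 shared barcodes. Matching with the suffix also left 243, which was fixed in advance because the suffix was a single value in both libraries. Counting distinct gene names gave 77924 features in place of 78241. Ignoring letter case left 190 list members, which could not change because all 190 had matched by exact name. Alternatives planned for transcript counts (cell filters, clustering resolution, doublet removal, scaling, the added constant and thinning) were not run, because counts were not analysed here. No paired analysis was possible because there was 1 library per group, and no library could be left out for the same reason. Limits on any statement about irradiation include this single library per group, the unknown cell load, and the donor marrow that only the irradiated mice received, which cannot be told apart from irradiation here.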

Other observations

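The tests in this part were chosen after the barcode lists had been seen. Some of the fixed marker genes share annotated sequence with a neighbour. This can matter for 3′ counting where the shared part lies near the 3′ end, because reads that fall on 2 genes of the same strand can be dropped. In GENCODE M21, 14 of the 190 fixed genes (7.37%) had an exon overlapping an exon of another gene on the same strand. Among the cell type markers these were the endothelial gene Egfl7 (with Mir126a and Gm20532), the fibroblast gene Pdgfra (Mir7025), the dendritic cell gene Clec9a (Clec1b), the T cell kinase gene Lck (Mir8119), the natural killer gene Klrb1c (Gm44511), the transcription factor gene Gata3 (9230102O04Rik), the plasma cell gene Mzb1 (SPATA24), the proliferation gene Top2a (Gm23451) and Spp1, which encodes osteopontin (Gm42793). Among the pathway genes they included Spp1 again, the apoptosis gene Bax (Gm45808), the collagen gene Col3a1 (Gm47302), the lysosomal protease gene Ctsd (Gm49369), and Zeb2 (Mir5129). None of the 8 contractile smooth muscle genes and none of the 8 macrophage genes had such an overlap in GENCODE M21. Only 65.8% of the listed Ensembl genes had an identifier there, so overlaps with the other listed genes could not be seen. Whether the neighbours named here were on the feature list was not checked. The neighbours named Mir and Gm47302 were annotated as microRNAs, and Gm23451 as a small nucleolar RNA. Whether an overlap lay at the 3′ end of the marker gene was not examined. Whether any of these overlaps changed a count was not tested.

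Barcodes that differ at 1 base occurred within libraries far more often than random combination of segments gives. There were 28 such pairs within the Control library (exact Poisson 95% interval 18.6 to 40.5; 0.790 expected) and 15 within the Irradiated library (8.40 to 24.7; 0.506 expected). Together they were 33.2 times the expected number, which argues against chance draws from the barcode pool. Between the libraries there were 2 such pairs against 1.33 expected. They were 1 pair of sequences counted in both directions, because both sequences were present in both libraries, and are not 2 independent pairs. Pairs that differ at exactly 2 bases showed no such contrast, with 9.01 per 1000000 possible pairs within Control, 8.91 within Irradiated and 9.14 between libraries.

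One explanation that stays open is a base change in the barcode of 1 droplet that gives another permitted barcode, so that 1 droplet is listed under 2 barcodes. Where such pairs can differ is set largely by the barcode set: 0 pairs of first segments and 63 pairs of second segments differed at 1 base, at positions 10 to 16 of the barcode (counted from 1 at the first base). Of the 43 pairs within libraries, 37 differed by a C-to-T change and 6 by an A-to-G change from the more common to the rarer segment, and 0 by the reverse changes, which random combination of the 63 permitted segment pairs would give in 33.7% of pairs. Also, 0 of the 43 differed at positions 15 or 16, where random combination would give 24.7%. Of the 68 barcodes with the rarer segment of a pair, 42 (61.8%) had a 1-base neighbour with a common segment in their own library. For 2 (2.94%), such a neighbour was in the other library. These shares restate the excess of pairs within libraries and do not tell a base change from another origin within a library. A base change requires no particular kind or position, so the kinds and positions do not decide for it. Counts per barcode, which could, were not analysed here. Most of the rare segments (the rarer member of a segment pair) had a property that may bear on why they were permitted: 24 of the 26 (92.3%), against 15.8% of the 3812 common ones, had a common counterpart with the complementary bases at the first 2 positions. This property was noticed in some of the same segments, so it is a hypothesis and no p-value is given. No biological explanation was tested. The pairs involve 53 Control barcodes (0.196%) and 30 Irradiated barcodes (0.0925%), too few to account for the ratio of barcodes between the libraries.

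The barcodes found in both libraries could in principle be carry-over of cells or reads between them. Chance alone gave 240.0 shared barcodes against 243 observed. The excess of 3.04 has an upper bound of 35.6, which argues against carry-over as the main source of the shared barcodes. Carry-over as the source of a smaller part of them stays open. The lists hold only barcodes of the filtered output, so they cannot show how many reads were carried over. With uniform draws from the pool of 3684480, about 99.6 barcodes of the Control library and 143 of the Irradiated library (0.368% and 0.440%) would be expected to stand for 2 droplets whose beads carried the same barcode. That is a calculation from the number of barcodes, and it was not measured.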
